A study of Mus musculus with 48 samples.

How the data were processed

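Total RNA from the cortex of 5xFAD and 5xFAD Plcg2+/- mice of both sexes was prepared with the PureLink RNA Mini Kit and hybridised by the standard NanoString protocol, per the labels' protocols, on the nCounter Neuropathology panel and the nCounter Glial panel. Samples were grouped by panel, genotype and sex as their titles give them, with 6 animals in each of 4 groups per panel, 24 animals and 48 samples in all. The animal numbers in the titles tie the 2 samples of an animal together across the panels.

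The deposited values are on a log2 scale. From the values themselves, each is the log2 of a whole number multiplied by 1 factor per sample. All 28398 values below 2000 counts came out whole within 0.002 once that factor was removed. These whole numbers were taken as the counts. A pseudocount or background subtraction in whole counts before scaling would not show in this check. How the authors set the factor, the software and the treatment of background are not given in the sources used here. Control probes were not used here. Because the deposited unit is log2, count models were not used; a fit with limma's voom precision weights on the recovered counts was added as an alternative. The recovered totals per sample ranged from 528033 to 1603006 on the Neuropathology panel and from 953461 to 1897264 on the Glial panel, which leaves counting error small for genes well above background. Each animal gave 1 sample per panel, so errors and p-values of single genes, background levels and total counts describe the spread between animals. That spread includes the handling of each sample. The camera p-values of the gene lists instead compare the genes of a list with the other genes. None of these values measures a spread between cohorts or runs.

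A gene was tested on a panel where its value was above 20 normalised counts in at least 6 of 24 samples, which left 715 of 760 genes on the Neuropathology panel and 700 of 757 on the Glial panel. Gene names were kept as in the deposited tables; 753 and 752 matched a mouse symbol of the reference table, 7 and 1 matched a synonym, and 4 on the Glial panel matched none. The probe C4a/b does not tell its 2 genes apart. The mean normalised count of the 45 and 57 genes below the filter served as a measure of background.

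Each panel was fitted separately with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) to the 4 group means of 24 samples. The contrasts were Plcg2+/- minus 5xFAD averaged over the sexes, the same within females and within males, the female minus male difference of that effect, and female minus male averaged over the genotypes. P-values were adjusted by Benjamini-Hochberg over the genes tested on a panel, and a gene was called at an adjusted p under 0.05. Errors given with ± are SD for group values and SE for fitted log2 fold changes. Gene lists, 23 in number and fixed before the data were examined, were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, where at least 5 members were tested. For the genes on both panels, the values of an animal were averaged over the panels, and, as a step added after the data were seen, subtracted to test whether the genotype effect differs between the panels. Background levels and total counts were compared within each sex by an exact two-sided permutation test of the difference in means.

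Genes named in the text follow a rule fixed together with the gene lists: per panel the 10 largest rises and 10 largest falls among genes called for genotype, up to 4 members of each list with the smallest p, up to 5 genes with the smallest p for each of the within-sex and interaction contrasts, and up to 10 for sex. Genes named for both panels together (Mtor, Hmox1, Bdnf, Homer1, Npas4, Cntf, Amph, and members of a list named on the other panel), and Sod1 and Park7, were chosen after their values were seen. The rule also named Plcg2, whose level was not analysed here. Some genes that the rule named are not reported here.

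Other settings tried were no low-value filter, a filter at 50 normalised counts, centring each sample on its median or on listed reference genes (3 tested on the Neuropathology panel and 2 on the Glial panel), quantile normalisation, eBayes with trend and robust settings, array weights, an additive model of genotype and sex, and fits within 1 sex. A fit without animals 12 and 3, background subtraction and voom weights were added after the data were seen. The fit was tested on simulated data in which 200 genes were changed by known amounts: for the genotype contrast on the Neuropathology panel (715 genes) it called 65.7% of genes changed by 0.25 on the log2 scale, 92.5% of those changed by 0.5 and 100% of those changed by 1, and 1.55% of unchanged genes; on the Glial panel (700 genes) the shares were 80.6%, 97.0%, 100% and 1.2%. The simulated noise was normal and independent between genes, without shifts of single samples or outlying animals. Fewer genes were changed than were called in the real data, so these shares may not carry over to it. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.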

Results

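Cortical RNA of 24 mice aged 7.5 months was measured with digital hybridisation counting on the NanoString nCounter Neuropathology and Glial panels, in which a barcoded probe pair is counted for each gene without amplification. The mice were 5xFAD animals, which carry mutated human transgenes and deposit amyloid in the brain, and 5xFAD animals heterozygous for Plcg2 (5xFAD Plcg2+/-). Plcg2 encodes phospholipase C gamma 2, a signalling enzyme of microglia and other immune cells. Each panel held 4 groups of 6 animals, 1 for each genotype and sex, and every animal was run on both panels. The comparison asks what reduced Plcg2 does to gene expression in a brain with amyloid. Plcg2 transcript levels were not analysed here, so the genotype labels could not be checked against them.

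Total counts per sample ranged from 528033 to 1603006 on the Neuropathology panel (760 genes) and from 953461 to 1897264 on the Glial panel (757 genes). The 5xFAD females had the lowest totals on the Neuropathology panel, between 528033 and 651615, against 1220459 to 1603006 in the Plcg2+/- females. Genes below the low-value filter had higher normalised counts in the Plcg2+/- groups. They averaged 11.6 ± 0.911 (SD, n = 6) in Plcg2+/- females against 6.67 ± 0.632 (n = 6) in 5xFAD females on the Neuropathology panel. In males they averaged 15.1 ± 1.08 (n = 6) in Plcg2+/- mice against 10.8 ± 1.65 (n = 6) in 5xFAD mice. The ranges of the genotypes did not overlap within either sex on either panel (exact two-sided permutation test, n = 6 per group, p = 0.00216, adjusted p = 0.00289 over 8 tests). Animal numbers ran from 1177 to 1270 in 5xFAD mice and from 3 to 51 in Plcg2+/- mice, so any difference between cohorts or runs cannot be told apart from genotype.

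On the Neuropathology panel, the immediate early genes Egr1 and Arc, which neurons switch on with activity, were about doubled in the cortex of Plcg2+/- mice. Egr1 rose from a log2 value of 11.52 ± 0.50 (SD, n = 12) in 5xFAD mice to 12.63 ± 0.32 (n = 12) in Plcg2+/- mice, and Arc from 8.83 ± 0.57 to 9.93 ± 0.36. Map2, which encodes a dendritic microtubule protein, fell from 12.26 ± 0.67 to 10.90 ± 0.99, and the microglial fractalkine receptor gene Cx3cr1 from 9.88 ± 0.31 to 8.76 ± 0.55. Parvalbumin (Pvalb) and Vip, markers of inhibitory interneurons, fell, while Tbr1, a transcription factor of deep-layer excitatory neurons, and Gad1, which makes GABA, rose.

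In the limma fit the log2 fold change was 1.10 ± 0.105 (SE) for Egr1 (adjusted p = 2.30e-08) and 1.10 ± 0.128 for Arc (adjusted p = 2.57e-07). All 12 Plcg2+/- animals lay above the 5xFAD mean of their sex for both. The other large rises belonged to genes with mean log2 values between 3.87 and 4.33, near the background. They were Cpt1b (log2 fold change 1.26), the T cell gene Cd8a (1.25), the scavenger receptor gene Marco (1.18), F2 (1.14), the cytokine gene Tnf (1.12), Napsa (1.06), Pla2g2f (1.03) and the dopamine receptor gene Drd4 (0.99). Large falls were seen in Map2 (-1.36 ± 0.288, adjusted p = 0.000295) and Cx3cr1 (-1.12 ± 0.167, adjusted p = 6.24e-06). Others belonged to the calcium channel subunit gene Cacnb4 (-1.11), the kinase gene Camk4 (-1.08), Sox9 (-1.02), the glutamate transporter gene Slc17a6 (-1.01) and the motor protein gene Kif3a (-0.98). Map2, Cacnb4 and Camk4 were each lower than the 5xFAD mean of the same sex in 10 of 12 Plcg2+/- animals. Plcg2+/- female 12 and male 3 stood apart from the rest of their groups, with Map2 values of 12.59 and 13.21, against 5xFAD means of 11.66 ± 0.15 (SD, n = 6) in females and 12.86 ± 0.30 (n = 6) in males. Their Cx3cr1 values were 9.62 and 10.08, against 9.66 ± 0.24 and 10.11 ± 0.17. On the Glial panel the log2 fold change of Map2 was only -0.27, with 8 of 12 animals in that direction. It was 0.03 in females and -0.56 in males there.

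In all, 508 of 715 genes tested differed between the genotypes on this panel, 233 higher and 275 lower in Plcg2+/- mice. The change was more than 2-fold for 18 of them. The median log2 fold change over all genes was -0.04. With each sample centred on its median, 497 genes were called with a split of 303 higher and 194 lower, and 427 of the 508 kept their call and sign.

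**Figure D1:**
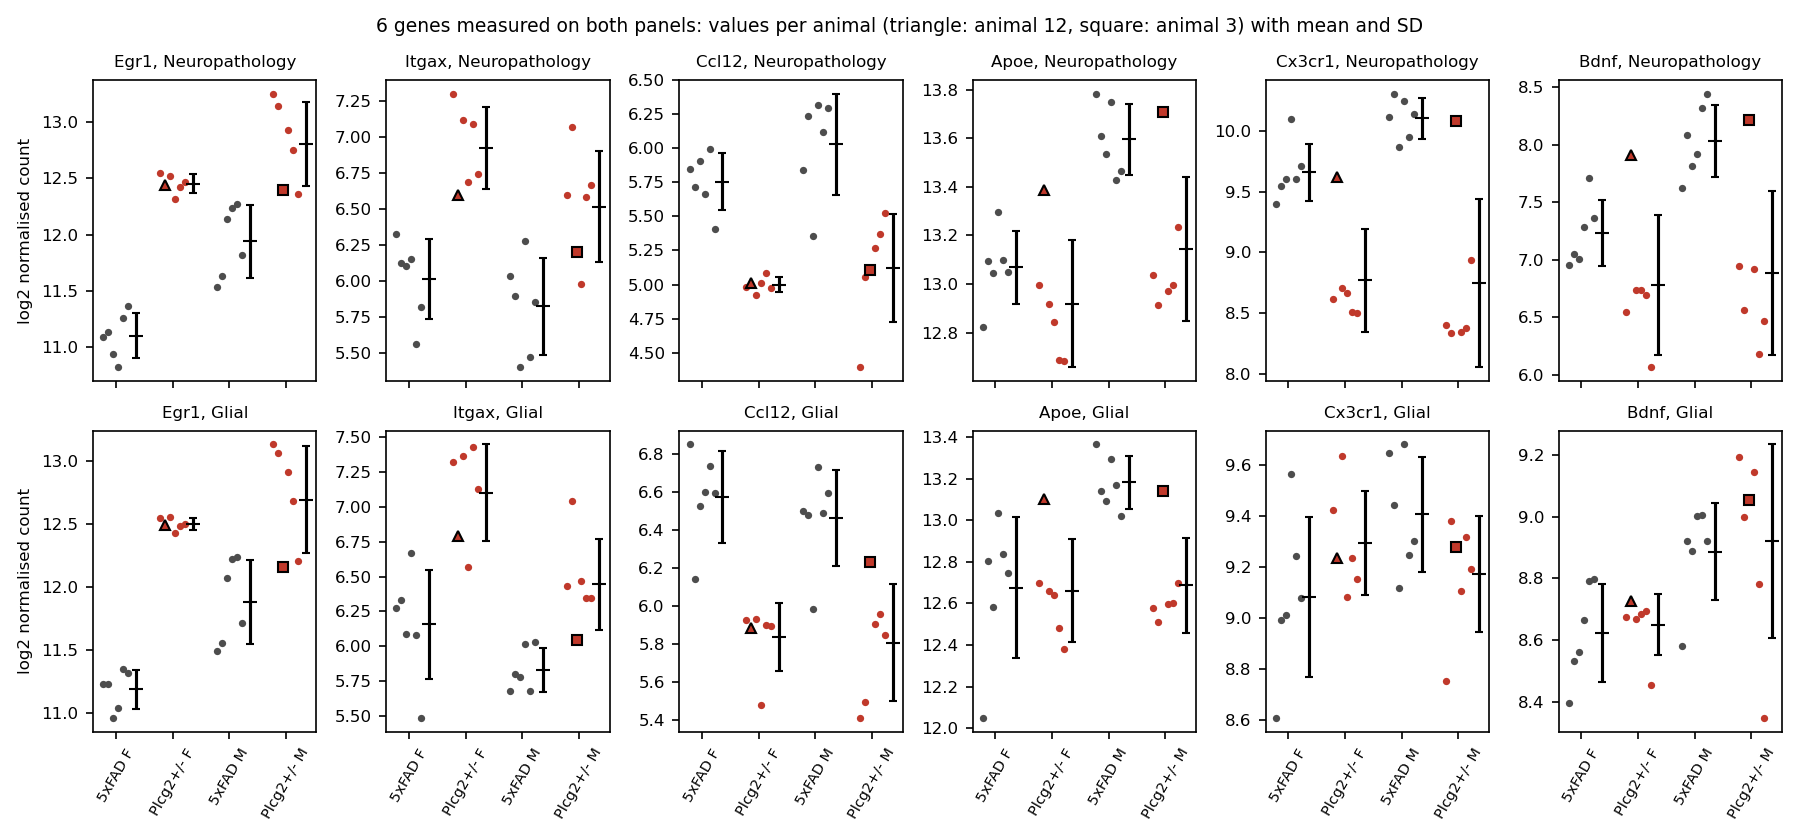
Log2 normalised counts of 6 genes measured on both panels (upper row Neuropathology, lower row Glial), with 1 point per animal, 6 animals per group, and the group mean with its SD in black; a triangle marks Plcg2+/- female 12 and a square Plcg2+/- male 3. Egr1 and Itgax were higher and Ccl12 lower in Plcg2+/- mice on both panels, whereas Cx3cr1 and Bdnf differed on the Neuropathology panel alone (log2 fold changes -1.12 and -0.80, against -0.01 and 0.03 on the Glial panel).

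On the Glial panel, Egr1 rose again, from 11.54 ± 0.44 (SD, n = 12) in 5xFAD mice to 12.60 ± 0.30 (n = 12) in Plcg2+/- mice, and Fos, another immediate early gene, rose from 7.36 ± 0.58 to 8.21 ± 0.29. Itgax, which encodes the integrin CD11c of activated microglia, rose from 5.99 ± 0.33 to 6.77 ± 0.47, and the complement probe C4a/b from 10.17 ± 0.42 to 11.04 ± 0.45. Gpr17, a receptor gene of oligodendrocyte precursors that are about to differentiate, rose from 7.24 ± 0.58 to 7.96 ± 0.22. The microglial marker Aif1, which encodes IBA1, fell from 8.73 ± 0.25 to 7.96 ± 0.27. Tmsb4x, an abundant actin-binding peptide gene, fell from 15.04 ± 0.15 to 14.26 ± 0.15, and the endothelial tight junction gene Cldn5 and the chemokine gene Ccl12 also fell.

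The log2 fold changes were 1.06 ± 0.108 (SE) for Egr1 (adjusted p = 4.47e-08), 0.87 ± 0.143 for C4a/b (adjusted p = 1.83e-05), 0.85 ± 0.156 for Fos (adjusted p = 6.90e-05), 0.78 ± 0.122 for Itgax (adjusted p = 1.01e-05) and 0.71 ± 0.0902 for Gpr17 (adjusted p = 7.02e-07). All 12 Plcg2+/- animals lay above the 5xFAD mean of their sex for Egr1, Fos, Itgax and Gpr17, and 11 of 12 for C4a/b. Tcl1 (0.99), Th (0.68), Ret (0.68), the chemokine gene Ccl2 (0.68) and Ltc4s (0.65) rose too, with mean log2 values between 3.89 and 4.86. The call of Ccl2 ended after background subtraction (0.22, adjusted p = 0.219) and that of Ltc4s with quantile normalisation (0.28, adjusted p = 0.0958). The falls were led by the cyclin gene Ccnh (-0.87), by Tmsb4x (-0.78 ± 0.0514, adjusted p = 6.99e-11), Aif1 (-0.77 ± 0.0977, adjusted p = 7.98e-07) and the mitochondrial fission gene Dnm1l (-0.72). Smaller falls were seen in the genes Eloc (-0.71), Ccl12 (-0.70), Cul2 (-0.65), Cldn5 (-0.64), Inpp5f (-0.64) and Arpc5l (-0.64). Tmsb4x, Aif1, Ccl12 and Cldn5 were lower in 12 of 12 animals.

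Of 700 genes tested on the Glial panel, 427 differed, 224 higher and 203 lower in Plcg2+/- mice, and only Egr1 by more than 2-fold. The median log2 fold change was 0.02. When samples were centred on the 2 listed reference genes tested on this panel, the split turned to 103 higher and 340 lower.

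Among the 242 genes tested on both panels, Egr1, Itgax, Fos, the receptor tyrosine kinase gene Ret, Mtor and the oxidative stress gene Hmox1 were higher in Plcg2+/- mice on both. Ccnh, Dnm1l, Ccl12, Cldn5, the tetraspanin gene Cd9, the myelin-associated gene Bcas1 and the complement gene C1qb were lower on both. Averaged over the panels in each animal, the log2 fold change was 1.08 ± 0.105 (SE, 12 animals against 12) for Egr1 and 0.79 ± 0.110 for Itgax. It was -0.88 ± 0.102 for Ccnh, -0.76 ± 0.0934 for Ccl12, -0.62 ± 0.0627 for Cd9 and -0.58 ± 0.150 for C1qb. Apoe, the lipid carrier gene of astrocytes and activated microglia, fell by 0.30 on the Neuropathology panel and by 0.25 on the Glial panel. Both calls were lost with quantile normalisation (-0.16, adjusted p = 0.107, and -0.23, adjusted p = 0.0547). The microglial receptor gene Trem2 fell by 0.42 on the Neuropathology panel, where 11 of 12 animals showed the direction, and by 0.26 on the Glial panel (adjusted p = 0.0458).

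Several genes were called on 1 panel and not on the other. Cx3cr1 (-1.12), Sox9 (-1.02), Camk4 (-1.08) and Slc17a6 (-1.01) fell on the Neuropathology panel, while their log2 fold changes on the Glial panel were -0.01, 0.09, -0.08 and -0.03. The within-animal difference between the panels was -1.11 ± 0.168 for Cx3cr1 (SE, 12 against 12). Csf1r, the receptor gene that microglia need for survival, fell by 0.39 on the Neuropathology panel and rose by 0.32 on the Glial panel. The progranulin gene Grn fell by 0.38 and rose by 0.45. The neurotrophic factor gene Cntf went the other way, rising by 0.44 on the Neuropathology panel although that rise was lost after background subtraction (0.35, adjusted p = 0.173), and falling by 0.49 on the Glial panel.

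The genotype effects of the 242 genes correlated between the panels (Pearson r = 0.626, Spearman rho = 0.620, across genes, which are not independent replicates). Of these genes, 181 had the same sign and 61 the opposite sign. Of the 130 genes called on both panels, 48 were higher on both, 63 were lower on both and 19 had opposite signs. The effect itself differed between the panels for 118 of the 242 genes, 48.8%, in a fit of the per-animal difference that was added after the data were seen. Each animal's Neuropathology profile over these genes correlated best with its own Glial profile in 22 of 24 animals, and with an animal of its own group in all 24.

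**Figure D2:**
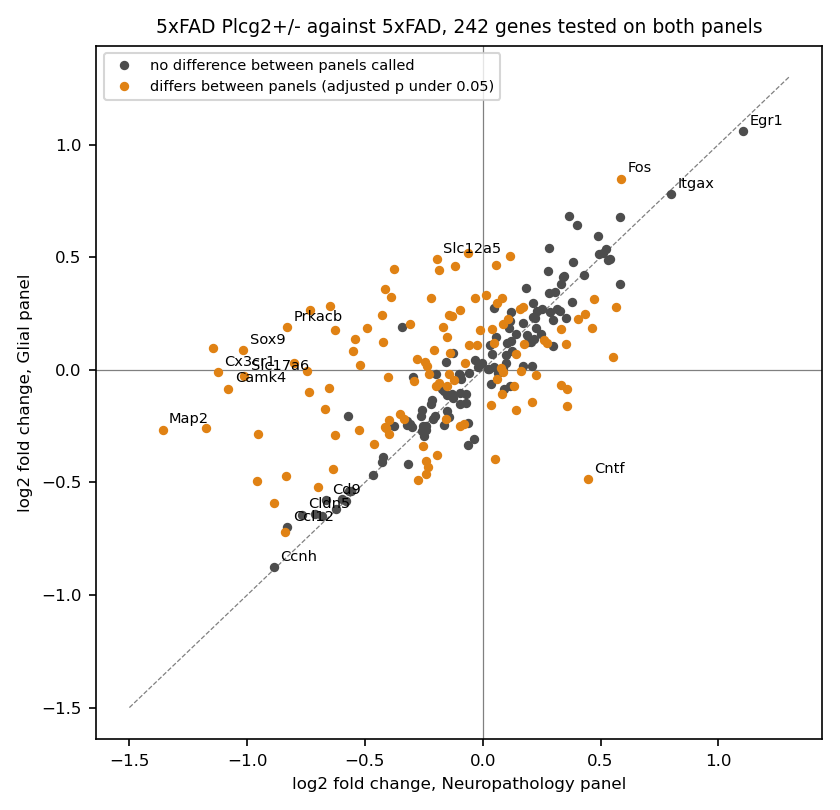
Log2 fold change of Plcg2+/- over 5xFAD mice on the Neuropathology panel (x axis) and the Glial panel (y axis) for the 242 genes tested on both, 12 animals per genotype, with equal values on the dashed line. The 118 genes in orange had a different effect on the 2 panels; Egr1, Itgax and Ccnh lie near the dashed line, and Cx3cr1 and Sox9 lie near 0 on the Glial axis alone.

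Members of the list of plaque-associated microglia, the state that microglia take on around amyloid, were more often lower than higher in Plcg2+/- mice. Itgax, the CD11c gene of activated microglia that is not on this list, went the other way. It rose on both panels, by 0.78 on the Glial panel, where 12 of 12 animals showed the direction. Of 25 members tested on the Glial panel, 10 fell and 4 rose, with falls of the ferritin gene Fth1 (-0.63, but -0.09 with adjusted p = 0.170 under quantile normalisation), Clec7a (-0.61), which encodes the receptor dectin-1, Cd9 (-0.58) and the adaptor gene Tyrobp (-0.39). Of 8 members on the Neuropathology panel, 5 fell, among them Cd9 (-0.67), Npc2 (-0.47) and Trem2 (-0.42), and Csf1 (0.29) rose. Animals 12 and 3 are part of these counts. On the main axis of the Glial panel male 3 (-0.02) lay among the 5xFAD males (-0.09 to 0.01), and female 12 (-0.03) lay between the 5xFAD females (-0.27 to -0.16) and the other Plcg2+/- females (0.09 to 0.14). In the list of pan-microglial identity genes, 7 of 17 members fell and 1 rose on the Glial panel, and 4 of 11 fell and 1 rose on the Neuropathology panel. Values were -0.77 for Aif1, -0.39 and -0.42 for C1qc and -0.58 on both panels for C1qb. The list around PLCG2 and its immunoreceptor partners had 7 of 13 members lower and 3 higher on the Glial panel, and 8 of 13 lower and 3 higher on the Neuropathology panel. Among the latter, the kinase gene Prkcb (-0.96), Prkce (-0.24) and Akt1 (-0.15, which turned to 0.03 with quantile normalisation) were lower and the calcium channel gene Itpr2 (0.35) was higher. Of all genes tested, 203 of 700 were lower and 224 higher on the Glial panel, and 275 of 715 lower and 233 higher on the Neuropathology panel. None of these lists passed camera on either panel.

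Homeostatic microglial genes were more often higher than lower on the Glial panel, where 8 of 21 rose and 3 fell. Of all 700 genes tested there, 224 were higher and 203 lower, and the list did not pass camera. The phagocytic receptor gene Mertk rose by 0.60 ± 0.0640 (SE, 12 of 12 animals, adjusted p = 7.93e-08), the fructose transporter gene Slc2a5 by 0.37 and Csf1r by 0.32. Of 8 tested on the Neuropathology panel, 2 rose, P2ry12 among them (0.27), and 3 fell, Cx3cr1, Csf1r (-0.39) and Fcrls (-0.35). Csf1r was thus called in opposite directions on the panels.

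Oligodendrocyte precursor genes were more often higher than lower. Of 7 members tested on the Glial panel, 6 rose and none fell, among them Gpr17 (0.71), the proteoglycan gene Cspg4 (0.52), the growth factor receptor gene Pdgfra (0.38) and Sox10 (0.36). Of 4 on the Neuropathology panel, 2 rose, Cspg4 (0.49) and Tnr (0.26). Camera gave this list an adjusted p of 0.0930 on the Glial panel (adjusted p = 0.944 with an estimated correlation), so it missed the threshold. Genes of mature oligodendrocytes and myelin went both ways, with 5 of 18 higher and 4 lower on the Glial panel and 6 of 18 higher and 3 lower on the Neuropathology panel. The myelin basic protein gene Mbp fell by 0.40 and Bcas1 by 0.62 while Fa2h rose by 0.34 on the Glial panel, and Ugt8a (0.46) and Myrf (0.35) rose on the Neuropathology panel.

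Astrocyte markers were mixed. Aldh1l1 rose on both panels (0.43 and 0.25), Kcnj10 rose on the Neuropathology panel (0.33), Egfr (0.52) and Slc1a3 (0.26) rose on the Glial panel, and S100b fell on both (-0.83 and -0.47). In all, 4 of 7 were higher on each panel, with 2 lower on the Neuropathology panel and 1 on the Glial panel. Of the pan-reactive astrocyte genes 3 of 8 rose on the Neuropathology panel, Hspb1 (0.48), Stat3 (0.21) and Cxcl10 (0.63). Of 5 on the Glial panel, Serpina3n (0.47) and Stat3 (0.29) rose and Vim fell (-0.22). Gfap did not pass on the Neuropathology panel (0.18, adjusted p = 0.0583), but did after centring on the median (0.30, adjusted p = 0.00307). With samples centred on reference genes, Stat3, Slc1a3 and Aldh1l1 lost their calls on the Glial panel (0.12, 0.08 and 0.07). Cltc, 1 of the 2 reference genes there, was itself higher in Plcg2+/- mice (0.42). The A1 list had 4 of 10 members lower and 1 higher on the Glial panel, led by H2-T23 (-0.41), and 1 of 2 in each direction on the Neuropathology panel. The A2 list had 2 of 9 higher and S100a10 lower (-0.54) on the Glial panel and 2 of 3 higher on the Neuropathology panel, with the prostaglandin synthase gene Ptgs2 at 0.42 and 0.43.

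Inflammatory genes went both ways. Of 21 cytokine and NF-kB members on the Neuropathology panel, 9 rose, Tnfrsf1a (0.45) and Tnf among them, and 3 fell, Ccl12 (-0.83), Il6 (-0.52) and Cxcl12 (-0.38). Of 13 on the Glial panel, 3 rose and 3 fell, the falls being Ccl12, Il18 (-0.36) and Ccl3 (-0.43). Complement genes fell for the C1q chains (3 of 7 lower on the Glial panel, C1qa at -0.38) and rose for C3 (0.69) and C4a (0.50) on the Neuropathology panel, where 3 of 6 rose and 2 fell. Interferon genes had 2 of 6 higher, Stat2 (0.28) among them, and 2 lower, Gbp2 (-0.27) and Ifnar1 (-0.10), on the Glial panel, and 1 of 2 higher on the Neuropathology panel. Centring on the median ended the calls of Gbp2 (-0.25, adjusted p = 0.0613) and Ifnar1 (-0.08, adjusted p = 0.113). Antigen presentation had 1 higher, Cd40 (0.38), and 2 lower, H2-T23 and Psmb8, of 8 on the Glial panel and 1 higher and 2 lower of 3 on the Neuropathology panel. The call of Cd40 was lost on both panels after background subtraction. Peripheral immune genes rose in 2 of 5 on the Glial panel, Cd163 (0.65) and Trac (0.55). They rose in 3 of 3 on the Neuropathology panel, Cd8a, Ccr2 (0.61) and Cd4 (0.35). The call of Ccr2 was lost after background subtraction (0.23, adjusted p = 0.301).

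Lysosomal genes were split, with 5 of 14 higher and 7 lower on the Neuropathology panel and 4 of 19 higher and 6 lower on the Glial panel. Npc1 (0.45) rose and Lamp1 (-0.67) and the proton pump gene Atp6v1h (-0.56) fell on the Neuropathology panel. Lipid handling genes rose in 4 of 5 on the Neuropathology panel, Lrp1 (0.55) among them, and fell in 4 of 5 on the Glial panel, where Acat1 (-0.31), Fabp5 (-0.22) and Lpl (-0.20) were lower. The members called on the panels differ apart from Apoe, which fell on both. Alzheimer risk and amyloid processing genes had 3 of 18 higher and 7 lower on the Neuropathology panel, with Cdk5r1 at -0.55 and Adam10 at -0.30. They had 6 of 15 in each direction on the Glial panel, with Bace1 (0.29) and Ptk2b (0.26) higher.

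Synaptic genes had 18 of 58 members higher and 27 lower on the Neuropathology panel and 15 of 36 higher and 8 lower on the Glial panel, where Shank2 rose (0.46). Neuron markers had 5 of 17 higher and 8 lower on the Neuropathology panel, with Pvalb at -0.65 ± 0.0419 (SE, 12 of 12 animals, adjusted p = 1.07e-10), Npy at -0.56, Vip at -0.45 and Tbr1 at 0.56. They had 3 of 11 in each direction on the Glial panel, with Tbr1 at 0.28 and Map2 at -0.27. Animals 12 and 3 are part of these counts. On the Neuropathology panel male 3 stood apart from its group in the mean log2 value of the synaptic list (10.69). Female 12 (9.32) and male 3 (9.81) did so for neuron markers. Endothelial genes had 3 of 16 higher and 6 lower on the Neuropathology panel, with Cldn5 at -0.77, Vegfa at -0.64 and Pecam1 at -0.32. They had 1 of 11 higher and 4 lower on the Glial panel, with Vegfa at -0.44, Emcn at -0.27 and Tjp1 at 0.31. Cell cycle genes fell in 3 of 5 on the Neuropathology panel, Ccnh, Ccnd1 (-0.82) and Pcna (-0.36), and in 2 of 4 on the Glial panel. Of the listed reference genes, Tbp (0.27) and Pgk1 (0.13) rose and Gusb (-0.28) fell on the Neuropathology panel. Cltc rose (0.42) on the Glial panel, while Pgk1 did not pass there (-0.07).

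Adjusted over the list alone, the counts were those given, apart from 5 of 7 astrocyte markers and 3 of 5 pan-reactive astrocyte genes higher, and 4 of 18 myelin genes higher, on the Glial panel. The list median and camera differed in sign for myelin on the Neuropathology panel (median -0.01, camera up) and, on the Glial panel, for complement (0.11, down), cytokines (0.02, down), antigen presentation (0.02, down) and neuron markers (-0.02, up). No list passed camera on either panel, with the preset or with an estimated correlation; the lowest adjusted p was 0.486 on the Neuropathology panel and 0.0930 on the Glial panel. Fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes, called lists both ways. On the Neuropathology panel its adjusted p was 7.43e-06 for lipid handling (up), 0.00185 for astrocyte markers (up) and 0.0136 for pan-reactive astrocytes and for cytokines (both up). It was 7.43e-06 for cell cycle (down), 0.00824 for the PLCG2 list (down), 0.00863 for endothelium (down), 0.0109 for plaque-associated microglia (down) and 0.0189 for neuron markers (down). On the Glial panel it was 2.86e-05 for oligodendrocyte precursors (up), 0.0175 for peripheral immune cells (up), 0.0310 for astrocyte markers (up), 0.0313 for pan-reactive astrocytes (up), 0.0316 for synaptic genes (up) and 0.0358 for homeostatic microglia (up). Down on that panel were lipid handling (8.10e-06), endothelium and the PLCG2 list (0.0263 each) and plaque-associated microglia (0.0358).

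**Figure D3:**
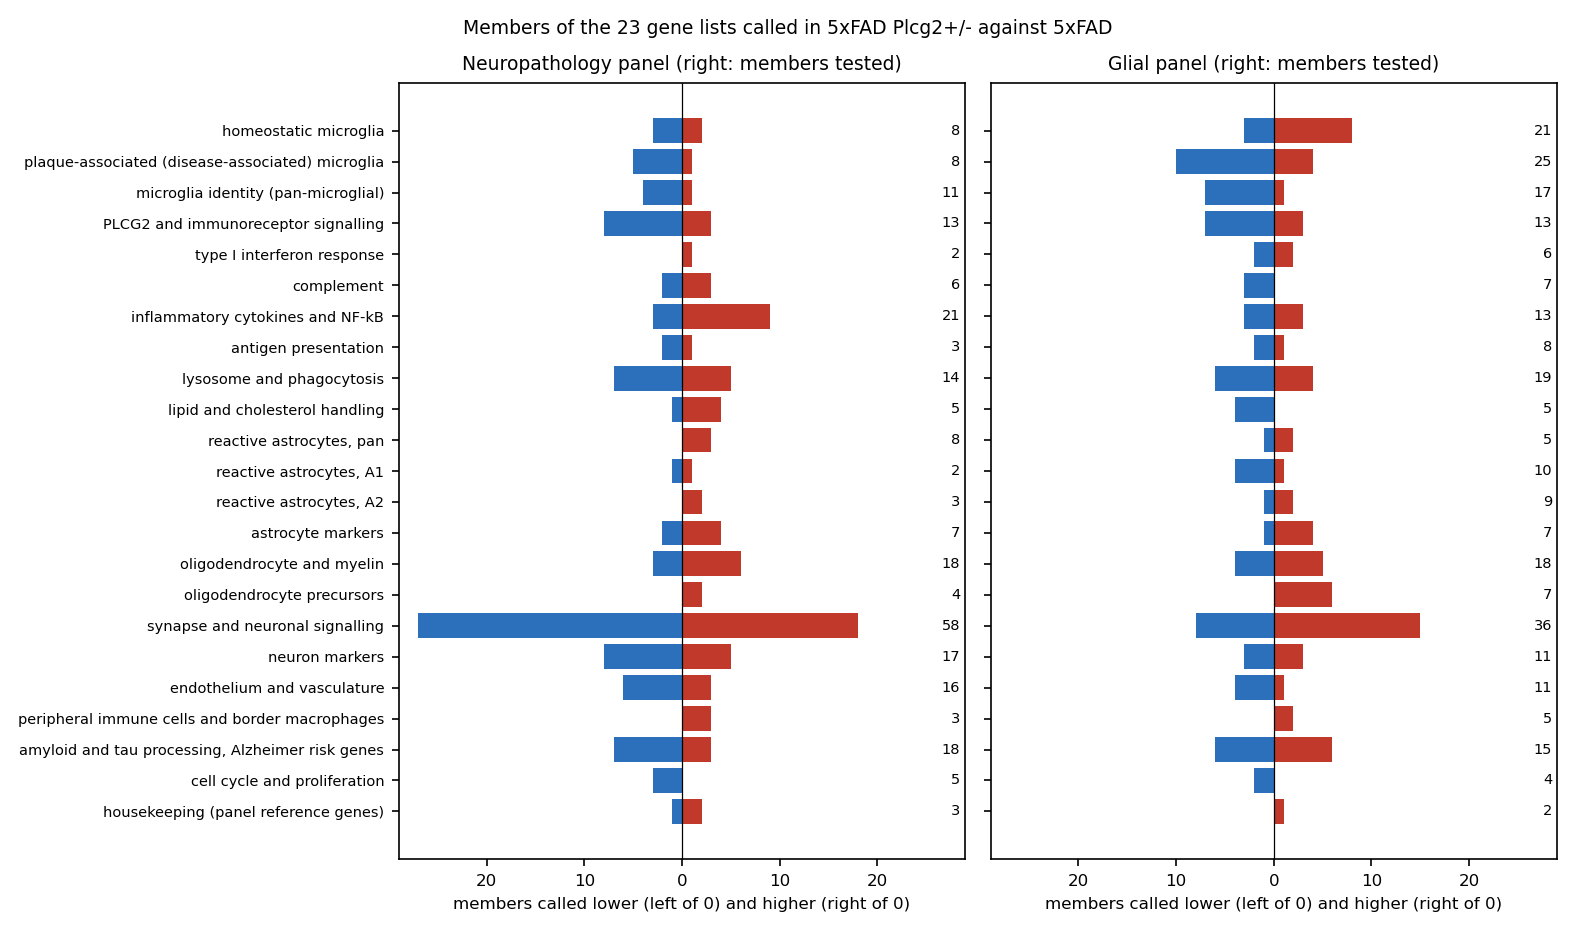
Number of members of each of 23 gene lists that were higher (red, right of 0) or lower (blue, left of 0) in Plcg2+/- mice at an adjusted p under 0.05, with the number of members tested at the right of each panel, 12 animals per genotype. Plaque-associated microglial genes had 10 of 25 members lower on the Glial panel, oligodendrocyte precursor genes 6 of 7 higher, and synaptic genes 27 of 58 lower on the Neuropathology panel. Of all genes tested, 203 of 700 were lower and 224 higher on the Glial panel, and 275 of 715 lower on the Neuropathology panel. No list passed camera.

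Within females, Tbr1 rose and Pvalb fell most clearly on the Neuropathology panel, and Tmsb4x, S100a10, Skp1a, Fth1 and Arpc1a fell most clearly on the Glial panel. Tbr1 rose by 0.79 ± 0.0565 (SE, adjusted p = 3.87e-10), the phosphatase gene Inpp4a rose by 0.56, and Pvalb (-0.83), Hras (-0.76) and Lsm7 (-0.70) fell, each in 6 of 6 Plcg2+/- females. Tmsb4x (-0.95), S100a10 (-0.81), Skp1a (-0.78), Fth1 (-0.71) and Arpc1a (-0.59) were also lower in 6 of 6. Within males, Vip (-0.48), the vesicle priming gene Unc13a (-1.15), the calcineurin gene Ppp3ca (-0.74) and Arsa (-0.61) fell and Gad1 (0.55) rose on the Neuropathology panel. In the same comparison Vegfa (-0.63), Bcas1 (-0.76), Tmsb4x (-0.62), Rbx1 (-0.45) and Fth1 (-0.56) fell on the Glial panel, each in 6 of 6 Plcg2+/- males. The calls of Fth1 in each sex were lost with quantile normalisation (adjusted p = 0.0650 in males).

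In all, 381 genes differed in females (237 higher, 144 lower) and 423 in males (132 higher, 291 lower) on the Neuropathology panel. The Glial panel gave 388 in females (234 higher, 154 lower) and 302 in males (123 higher, 179 lower). In males the split depended on the scaling, with 308 higher and 160 lower on the Neuropathology panel and 194 higher and 134 lower on the Glial panel after centring on the median. With quantile normalisation it was 238 higher and 196 lower, and 175 higher and 155 lower. It was 14 higher and 469 lower on the Glial panel after centring on reference genes.

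The genotype effect differed between the sexes for Mmp24 and Shc3 among others. Female minus male, the difference in log2 fold change on the Neuropathology panel was 0.64 for Mmp24, 0.58 for Pcsk2, 0.49 for the myosin gene Myh10 and 0.39 for Inpp4a. It was 0.78 for Shc3, 0.67 for Adcy1, 0.60 for Camk2a and 0.55 for Adcy5 on the Glial panel, where the proteasome gene Psmd6 went the other way (-0.47). Vascular genes of the Glial panel had a median difference of 0.41, with 7 of 11 members called higher and none lower (camera adjusted p = 0.00407, adjusted p = 0.511 with an estimated correlation). In males alone 7 of 11 fell (camera adjusted p = 0.0208, adjusted p = 0.924 with an estimated correlation).

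The test called 159 genes with an interaction on the Neuropathology panel (143 higher, 16 lower) and 166 on the Glial panel (114 higher, 52 lower). The median difference over all genes was 0.21 and 0.08, a shift between whole samples that each gene's difference contains. After centring on the median, 114 genes were called on the Neuropathology panel, 26 higher and 88 lower, 42 of them among the 159. The split on the Glial panel turned too, to 85 higher and 93 lower after that centring and to 81 and 99 with quantile normalisation, while centring on reference genes gave 284 higher and 6 lower. Myh10 (0.22, adjusted p = 0.113) and Inpp4a (0.12, adjusted p = 0.470) lost their calls, and Mmp24 (0.37), Pcsk2 (0.31) and the 5 Glial genes kept theirs. The count depended on 2 animals: without Plcg2+/- female 12 and male 3 it was 324 on the Neuropathology panel and 233 on the Glial panel.

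Between the sexes, almost all genes had lower values in females, with a median female minus male difference of -0.43 on the Neuropathology panel and -0.26 on the Glial panel, where 629 of 715 and 542 of 700 genes were called lower. Relative to that shift, with samples centred on the median, Lmna (-0.28), Magee1 (-0.21), Ap2a2 (-0.21), Myh10 (-0.21), Sf3a2 (-0.20), Gprasp1 (-0.19), Pqbp1 (-0.15), Inpp4a (-0.14) and Ddx23 (-0.14) stayed lower in females on the Neuropathology panel, and Camk2d did not pass (-0.08, adjusted p = 0.258). With quantile normalisation Inpp4a (-0.10, adjusted p = 0.108) and Gprasp1 (-0.11, adjusted p = 0.0720) did not pass either. Emcn (-0.47), Hsp90ab1 (-0.46), Nefh (-0.40), Atp9a (-0.36), Adcy5 (-0.33), Trim35 (-0.31), Slc25a12 (-0.28), Sqstm1 (-0.25), Nmnat2 (-0.20) and Camk2d (-0.15) stayed lower on the Glial panel. Microglial and other immune genes stood out from the shift. Of 25 plaque-associated microglial genes on the Glial panel, 13 were higher in females and 6 lower, with a median of 0.17 (camera adjusted p = 1.40e-16, adjusted p = 0.0328 with an estimated correlation). Of 17 pan-microglial genes, 8 were higher and none lower. On the Neuropathology panel 1 of 8 plaque-associated genes was higher and 4 were lower (adjusted p = 0.0672 with an estimated correlation), and 1 of 11 pan-microglial genes was higher and 1 lower (adjusted p = 0.0127). With an estimated correlation, complement (adjusted p = 0.00725) and cytokine genes (adjusted p = 0.0118) also lay above the shift there. After centring, 184 genes differed on the Neuropathology panel (59 higher, 125 lower) and 285 on the Glial panel (99 higher, 186 lower).

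**Figure D4:**
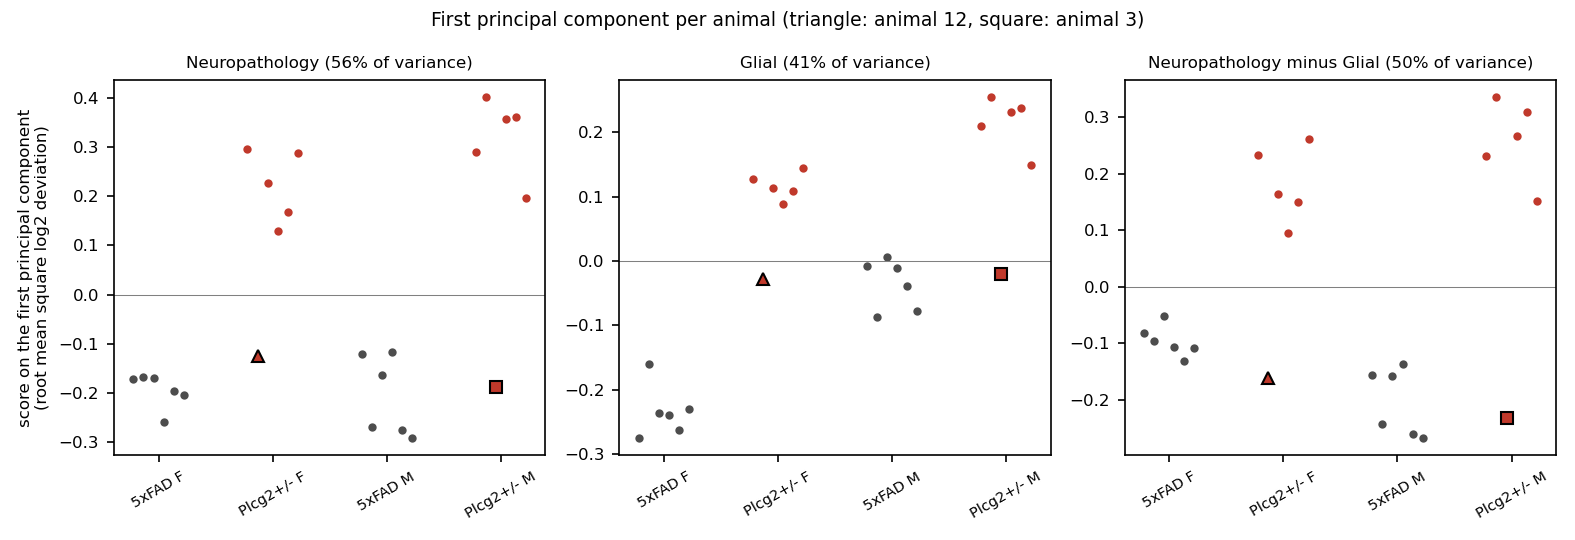
Score of each animal on the first principal component of the median-centred log2 values on the Neuropathology panel, on the Glial panel and of the within-animal difference between the panels over 242 shared genes, with 6 animals per group; a triangle marks Plcg2+/- female 12 and a square Plcg2+/- male 3. On the Neuropathology panel the 5xFAD females lie between -0.26 and -0.17 and the 5xFAD males between -0.29 and -0.12. Animal 3 (-0.19) lies among these males, animal 12 (-0.13) lies above these females, and the other 10 Plcg2+/- animals lie between 0.13 and 0.40.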

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

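All tests of explanations in this part were chosen after the results they bear on had been seen. A sample was singled out where its gap to the nearest other sample of its group of 6 exceeded 0.625 of the range of the group. That happened 43 times in 336 checks, 37 times for Plcg2+/- female 12 or male 3, where chance alone, at about 1 in 20 groups, would give 16.8.

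On the main axes of variation, female 12 stood apart on the Glial panel (-0.029), and male 3 on the Neuropathology panel (-0.19) and in the difference between the panels (-0.23). In mean log2 value over a gene list on the Neuropathology panel, male 3 stood apart for the PLCG2 list (10.26), amyloid and risk genes (10.60), astrocyte markers (10.18), cell cycle (8.62), pan-microglial genes (9.40), neuron markers (9.81), plaque-associated microglia (9.82) and synaptic genes (10.69). Female 12 did so for amyloid and risk genes (10.23) and neuron markers (9.32), and male 3 for the PLCG2 list on the Glial panel (9.51).

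Among single genes of the Neuropathology panel, male 3 stood apart for Map2 (13.21), Cx3cr1 (10.08), Cacnb4 (10.29), Camk4 (10.99), Sox9 (9.14), Slc17a6 (8.58) and Kif3a (10.19), and female 12 for Arc (10.09), Map2 (12.59), Cx3cr1 (9.62), Sox9 (8.56), Slc17a6 (7.96) and Kif3a (9.62). On the Glial panel male 3 stood apart for Aif1 (8.48), Dnm1l (10.79), Cul2 (9.72) and Inpp5f (10.69), and female 12 for C4a/b (10.33), Dnm1l (10.39) and Arpc5l (9.79). The others were 5xFAD male 1182 for cytokine genes on the Neuropathology panel (5.96) and Ccl12 on the Glial panel (5.99), 5xFAD male 1269 for synaptic genes on the Glial panel (11.03), 5xFAD female 1248 for Cd8a (0.45), and Plcg2+/- female 18 for Ltc4s (3.27) and Ccl12 (5.48) on the Glial panel.

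The test of the difference itself called a genotype effect that differed between the sexes for 159 genes of the Neuropathology panel and 166 of the Glial panel. After centring on the median, 42 and 137 of these kept their call and sign, and 26 and 75 did so under every alternative. Another split of the samples gave 241 genes on the Neuropathology panel, so chance is not excluded for the count there. The female minus male differences were 0.49 for Myh10, 0.64 for Mmp24, 0.58 for Pcsk2, 0.39 for Inpp4a, 0.78 for Shc3, 0.60 for Camk2a, 0.67 for Adcy1, 0.55 for Adcy5 and -0.47 for Psmd6, and the median over vascular genes of the Glial panel was 0.41. Centring on the median ended the calls of Myh10 (0.22, adjusted p = 0.113) and Inpp4a (0.12, adjusted p = 0.470), and the vascular list did not pass with an estimated correlation (adjusted p = 0.511). The level of genes below the filter, which no comparison of genes used, lay above that of the 5xFAD animals in Plcg2+/- females (11.6 on the Neuropathology panel and 10.8 on the Glial panel) and males (15.1 and 14.2).

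Genes near the background rose in Plcg2+/- mice, among them Tnf, Cd8a and Ccl2. On the Neuropathology panel 27 of the 56 genes with a mean log2 value under 6 that were called higher, 48.2%, stayed called after background subtraction, and their median log2 fold change went from 0.57 to 0.38, so a higher background may account for part of the rise. On the Glial panel 13 of 22 stayed, 59.1%, with a median of 0.55 before and 0.53 after, which decides neither way, so there background and expression cannot be told apart for these genes. Higher total counts are not the source of the background in Glial males, where totals did not differ by the test (exact permutation p = 0.944) and the background still stood at a ratio of 1.28. Cohort and genotype remain open together, since the animal numbers part the genotypes.

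The genotype effect of 118 of 242 shared genes depended on the panel, with Cx3cr1 and Sox9 as examples. The dependence was not confined to genes near background, since 94 of the 164 genes over log2 8 on both panels differed (57.3%, against 48.8% of all). These shares count calls, which also depend on how precisely a gene is measured. They therefore cannot tell how much background adds for the lower genes. Sample scaling does not remove it, since 120 genes differed after centring on the median (70 with a higher effect on the Neuropathology panel and 50 lower, against 36 and 82). An even change of the whole transcript would by itself give the same sign on both panels, which the 19 genes called with opposite signs did not show. That their effects also differed between the panels nearly follows from the opposite calls and adds little. Whether scaling or background on a single panel turned the sign of these 19 genes was not tested. Probes that read different parts or forms of a transcript, and a run or RNA quality difference that acts on the panels unequally, might be involved and were not tested.

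Animal 3 lay near the 5xFAD males, and animal 12 lay between the genotypes. Of the genes that separate the other animals of their sex, 45.1% for animal 12 and 15.9% for animal 3 on the Neuropathology panel, and 56.9% and 16.3% on the Glial panel, lay on the Plcg2+/- side. The highest shares were 26.0% and 31.0% in 5xFAD females and 9.57% and 16.5% in 5xFAD males, and each of the other Plcg2+/- animals had at least 75.6%. For Egr1, animal 12 lay above every 5xFAD female on both panels (12.44 against at most 11.37, and 12.49 against at most 11.35). Animal 3 lay above every 5xFAD male on the Neuropathology panel (12.39 against at most 12.27) and among them on the Glial panel (12.16 against at most 12.24). Since the animal numbers part the genotypes, a difference between cohorts could also raise Egr1. A swap with a 5xFAD animal of the series needs a partner out of place, and the highest share in any 5xFAD animal was 31.0%. A sample state that changes the panels unequally cannot be told apart from a wrong label. Animal 12 scored -0.16 and animal 3 scored -0.23 on the main axis of the panel difference, but that axis itself parts the 5xFAD animals (-0.27 to -0.05) from the other 10 Plcg2+/- animals (0.10 to 0.34). A wrong genotype label stays open, since 0 of the genes analysed are named Plcg2. A biological difference between animals was not tested.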

How the results depend on the processing

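The fits without animals 12 and 3, with background subtraction and with voom weights, and the test of the panel difference, were chosen after the data had been seen; the others were planned. Among single named genes, 1732 planned comparisons kept their status as called or not called, 41 lost the call, 21 gained it and 4 reversed. Of the added ones 679 kept their status, 6 lost the call and 2 gained it. A change of sign counted as a reversal only where the gene was called in the main fit or the alternative, and as kept otherwise. Of the 508 and 427 genes called for genotype on the Neuropathology and Glial panels, 326 and 258 were called with the same sign under every alternative, where a gene left untested counted as not called. The correlation between the panels ranged from 0.613 to 0.635. No paired analysis was possible because the compared groups share no animal numbers. A pseudocount of 10 was not tried since the values are already log2, and the Plcg2 level was not analysed. Signal near background limits genes under a log2 value of about 6.

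For the following changes the cause was not tested, apart from the shift that centring on reference genes brings by construction. After centring on the median, the sex effect gave 184 genes on the Neuropathology panel (59 higher, 125 lower) and 285 on the Glial panel (99 higher, 186 lower), and the interaction on the Glial panel 178 (85 higher, 93 lower). Quantile normalisation gave 182 (81 higher, 101 lower) and 293 (133 higher, 160 lower) for sex, 93 (39 higher, 54 lower) and 180 (81 higher, 99 lower) for the interaction, and turned Akt1 to 0.033 and Cdk2 to -0.25 on the Neuropathology panel. Centring on reference genes rests on 2 genes on the Glial panel, Cltc and Pgk1. There it gave 218 genes for sex (104 higher, 114 lower), 290 for the interaction (284 higher, 6 lower) and 483 in males (14 higher, 469 lower). Camera then called 1 list, oligodendrocyte precursors (adjusted p = 0.00296, against 0.0608 to 0.129 in the other settings with the preset correlation), and Nefh turned to -0.039. Cltc itself had log2 fold changes of 0.28 in females and 0.56 in males, and Pgk1 of -0.16 and 0.02. Centring subtracts the mean of these 2 genes from every gene. By construction it thus lowers the male effects and raises the female minus male differences. Array weights gave 368 interaction genes on the Neuropathology panel (316 higher, 52 lower) and 273 on the Glial panel (164 higher, 109 lower). Without animals 12 and 3 the interaction on the Neuropathology panel rose to 324 (291 higher, 33 lower), and the genotype effect gave 542 and 454 genes. With no filter 1 list was called on the Glial panel, peripheral immune cells (adjusted p = 0.0240), with 23 members tested instead of 5.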

Other observations

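The test of complete separation and that of activity-induced genes were chosen after the data had been seen; the counts over other splits of the samples were run for each count of genes, with their expectation written afterwards.

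Some genes separated the genotypes without overlap in both sexes. On the Neuropathology panel 22 of 715 genes were higher and 26 lower in every Plcg2+/- animal than in every 5xFAD animal of the same sex, and on the Glial panel 7 of 700 were higher and 27 lower, where chance gives 0.000234% of genes. Amph, which encodes the nerve terminal protein amphiphysin, was higher on both panels (0.33 and 0.38), and Cd9 and Bcas1 were lower on both. Sod1, the superoxide dismutase gene, was lower on the Glial panel (-0.46), and Park7, a gene of oxidative stress defence, was lower on the Neuropathology panel (-0.43). These animals include 12 and 3.

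The higher Egr1, Arc and Fos may point to a joint rise of genes that neuronal activity induces. Of Arc, Bdnf, Egr1, Fos, Homer1 and Npas4, 2 were called lower on the Neuropathology panel, Bdnf (-0.80) and Homer1 (-0.35), while Npas4 rose (0.52). Bdnf did not differ on the Glial panel (0.03, adjusted p = 0.753), so its fall depended on the panel. These 6 genes thus did not all rise, but whether activity lies behind the rises of Arc, Egr1, Fos and Npas4 is left open.

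The counts were also taken over 100 splits of the samples into groups of the same sizes, the real one included. The real split gave the most genes for the genotype effect (508 against a highest other of 147 on the Neuropathology panel, 427 against 62 on the Glial panel). It also did so in females (381 against 317, and 388 against 324) and in males (423 against 388, and 302 against 292). The same held for the interaction on the Glial panel (166 against 46) and for sex (636 against 492, and 579 against 342). In each case 1 of the 100 splits was as large, the real one itself, which is the smallest share that 100 splits can give. The margin was narrow in males. Splits of the samples cannot tell genotype from a difference between cohorts. For the interaction on the Neuropathology panel 2 of the 100 splits were as large as the real 159 genes, the real one included. The highest other gave 241 genes, more than the real one, so chance is not excluded for this count. For the gene lists camera called 0 on either panel, so all 100 splits had to give as many (highest other 4 and 8), and this count decides nothing about chance.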
